A study of Homo sapiens with 2 samples.

How the data were processed

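In situ Hi-C captures pairs of genomic fragments that lie close together in the nucleus, by cutting crosslinked chromatin, joining the cut ends and sequencing the junctions. Per the labels' protocols, HEK293T cells (a human embryonic kidney line that carries the SV40 large T antigen) were fixed with formaldehyde, the chromatin was cut with MboI, the ends were filled with biotinylated nucleotide and ligated, and the captured fragments were made into Illumina libraries. The series held 2 libraries of 1 group, labelled as replicates 1 and 2, and no treated, depleted or control group. Nothing in the labels says that they came from separate cultures.

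All 3 deposited tables describe the group as a whole, with no column for either library. How the replicates were combined is not given in the sources used here. No spread between replicates can therefore be given, and neither library could be left out. Per the submitters' processing notes, FastQC 0.11.7, BWA 0.7.8 and Picard were used and the genome build was hg19. The submitters' notes name no roles for these tools. The number of reads or valid contacts per library is unknown here, and the contacts counted in each loop pixel are the only measure of depth.

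Per the names and values of the deposited files, the compartment table gives 1 score for each 1 Mb bin. The authors' method for that score, its normalization and its sign convention are not given in the sources used here. The squares of the scores sum to 1 on each chromosome, as for an eigenvector, so levels cannot be compared between chromosomes. The domain table lists contact domains called on 5 kb bins, and the second of its columns named score, with the caller's own score per domain, was used as deposited. The domain caller is not given in the sources used here. The loop table was made with HiCCUPS at 5 and 10 kb and merged, per the deposited file's name. Per the file headers it holds the observed count of contacts in each loop pixel, the contacts expected from 4 local neighbourhoods (donut, lower left, horizontal and vertical), and an FDR for each. The authors' FDR columns are q-values, and the highest in any of the 4 was 0.0999. These tables list only features that passed a caller's threshold, so a region without a domain or loop is one with none listed.

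Bins were called positive or negative by the sign as deposited. Which sign is the gene-rich A compartment was planned to be settled by gene density, but the gene table supplied was of another build (GRCh38), so no gene was placed on these coordinates. For the same reason the planned comparisons of gene density and gene lists between signs, of genes at loop anchors and domain boundaries, and of CTCF motif orientation were not run, and the text names regions rather than genes. A domain was assigned to the bin of its midpoint and a loop anchor to the bin of its centre. Distances between anchors are start to start. Positions are counted from 1, with both ends included. Enrichment is the observed count divided by the donut expectation, and its 95% interval is the exact Poisson interval of the observed count with the expectation held fixed. The enrichment over the highest of the 4 expectations was computed likewise, as an addition made after the data were seen. These intervals, and the Wilson intervals of shares, cover counting error only.

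Relations between tables were tested with two-sided circular-shift permutation tests. Signs were rotated along the valued bins of each chromosome, independently for each, in 100000 draws, which keeps runs of neighbouring bins together. Loops were set against domains by rotating the loops along the chromosome, with 1000 shifts per chromosome recombined in 100000 draws. A loop was at a domain corner when its anchors lay within the larger of 50 kb or 0.2 of its length of both ends of 1 domain. The 7 tests formed 1 family for Benjamini-Hochberg adjustment, with a threshold of 0.05. The smallest p these draws can give is 1e-05. The p-values treat regions of 1 pooled map as the units and say nothing about other cultures. Intervals on ratios and medians come from resampling the 23 chromosomes, in 1000 draws for ratios and 2000 for medians. The rotation tests were tested on simulated points placed independently of one another. With no difference put in, 6% of 100 simulated sets of 3845 domains passed the threshold, as did 6% of 100 simulated sets of loop anchors and 6% of 100 sets of domain lengths. With a 1.2-fold difference in density or a log2 length difference of 0.2, 100% passed. In the data, loop anchors come in pairs. Neither that nor any likeness of neighbouring domains was simulated, so these rates may not hold for the data. For domain corners, 5% of 20 simulated sets passed with no loops placed at corners and 100% with 10% placed there.

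Before the data were examined, the tests, the alternatives and the rule for named regions were fixed. The rule named the 5 bins with the highest and the 5 with the lowest scores, the 8 domains with the highest scores and the 3 longest, the 12 loops with the highest enrichment among those with at least 20 contacts, and the 3 longest loops. The other settings fixed then were only bins in the outer 2 of 3 parts by absolute score, autosomes only, high-scoring or innermost domains, domains wholly within 1 sign, a stricter loop FDR of 0.01, each anchor width alone, and smaller corner tolerances. After the data were seen, chromosomes whose score was carried by a few bins (an effective number of bins, the inverse of the summed squared shares, under 10% of the valued bins) were left out as an alternative, as was chromosome 4, loops over 2 Mb were set apart, and a shift of at most 1 Mb was added for domain corners. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.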

Results

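The series asked how the chromatin of HEK293T cells is folded, at the scale of A and B compartments, contact domains and loops. It belongs to work on the NuRD chromatin remodelling complex and the insulator protein CTCF, but both of its libraries are of cells labelled with no treatment other than crosslinking. The 3 genome-wide tables cover chromosomes 1 to 22 and X, and positions are in hg19 coordinates counted from 1. The compartment table held 3053 bins of 1 Mb, of which 2883 carried a score. The domain table listed 3845 contact domains and 1507 loops were called. The observed contacts per loop pixel ranged from 13 to 349, with a median of 74. All values are the authors' calls on both libraries together, so no value below has a replicate error, and the design holds no second condition.

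Compartment scores were positive in close to as many bins as they were negative over all chromosomes together, though the share differed between sets of chromosomes. Of the valued bins, 1408 were positive and 1473 negative, and 2 were 0. Positive bins made up 48.9% of the signed bins (95% Wilson interval 47.0 to 50.7%). The Wilson intervals in this paragraph treat bins as independent. Neighbouring scores were correlated on most chromosomes, so these intervals are too narrow. The share was 50.5% (48.6 to 52.4%) on the autosomes. It was 58.3% on chromosomes 5, 11, 13, 14 and 22, whose scores were carried by a few bins, with 96 of 97 bins positive on chromosome 13 and 33.3 to 52.5% on each of the other 4. It was 46.7% (44.7 to 48.8%) without them and 44.3% (42.2 to 46.4%) without them and chromosome 4. On most chromosomes the signs formed blocks of several megabases. Over all chromosomes there were 270 positive runs and 278 negative runs, each with a median length of 3 Mb. Chromosome 1 had 108 positive and 122 negative bins, 33 sign switches and a correlation of 0.879 between neighbouring bins. That correlation ranged from 0.581 on chromosome 18 to 0.932 on chromosome 4 outside chromosomes 5, 11, 13, 14 and 22. The longest positive run of chromosome 1 spanned 6 to 48 Mb, which was the longest outside chromosomes 4, 5, 11, 13, 14 and 22. On chromosome X, 122 of 151 valued bins were negative, including an unbroken negative run from 61 to 118 Mb.

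On chromosomes 5, 11, 13, 14 and 22 most of the squared score lay in a few bins rather than in blocks. Their signs could still form long runs. The longest positive run of all spanned 21 to 116 Mb of chromosome 13, and the longest negative run 49 to 131 Mb of chromosome 5. A single bin carried 97.9% of the squared score of chromosome 13, 79.6% of that of chromosome 22, 58.3% on chromosome 5, 57.4% on chromosome 11 and 42.3% on chromosome 14. On the other 18 chromosomes the top bin carried between 1.22% (chromosome 2) and 6.20% (chromosome 21). Because scores are scaled within each chromosome, this concentration by itself places the 5 lowest and the 5 highest scores on those 5 chromosomes, and their levels have no meaning between chromosomes. The lowest was -0.989 at 20 to 21 Mb of chromosome 13, the only negative bin of that chromosome, against 96 positive bins. The next were -0.763 at 1 to 2 Mb of chromosome 5, -0.758 at 78 to 79 Mb of chromosome 11, -0.650 at 56 to 57 Mb of chromosome 14 and -0.355 at 21 to 22 Mb of chromosome 22. The highest was 0.892 at 20 to 21 Mb of chromosome 22. It was followed by 0.535 at 2 to 3 Mb of chromosome 5, 0.490 at 49 to 50 Mb of chromosome 14, 0.435 at 79 to 80 Mb of chromosome 11 and 0.342 at 55 to 56 Mb of chromosome 14. Bins of opposite extreme score were thus direct neighbours on chromosomes 5, 11, 14 and 22.

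Chromosome 4 departed in another way. Its sign followed the chromosome arms, taken as the bins on either side of the longest interior stretch without scores. In the first arm 46 of 50 bins were negative, and in the second 137 of 140 were positive, so that 96.3% of bins matched their arm. The next highest match was 78.7%, on chromosome 20. Chromosome 4 had 8 sign switches, against 35 on chromosome 3, which is of similar length.

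**Figure D1:**
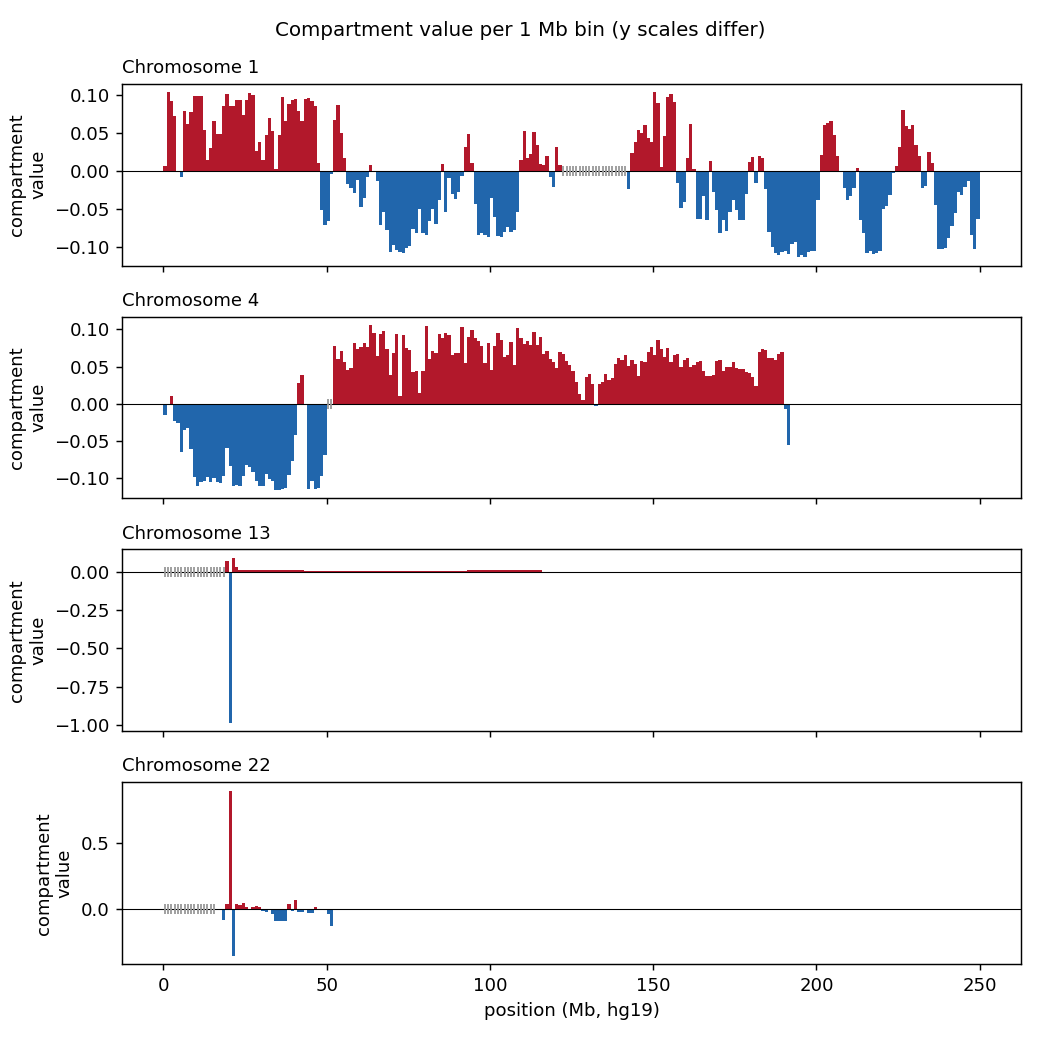
Compartment score (y axis, no unit, scales differ between panels) of each 1 Mb bin along chromosomes 1, 4, 13 and 22 (x axis, Mb, hg19). Red bars are positive, blue bars negative and grey ticks bins with no score. Chromosome 1 alternates in blocks, chromosome 4 changes sign between its arms, and a single bin dominates chromosomes 13 (-0.989) and 22 (0.892).

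Contact domains are stretches within which contacts are more frequent than with the neighbouring sequence. The 3845 domains had a median length of 235 kb (interval 220 to 250 kb, chromosomes resampled), with quartiles at 140 and 405 kb and a range of 60 to 3505 kb. Together they covered 1203 Mb, or 41.7% of the valued genome length of 2883 Mb. Of these domains, 149 were longer than 1 Mb and 246 (6.40%) held a smaller listed domain. Chromosome 17 had the most domains per megabase (2.15), followed by chromosomes 10 (1.90), 1 (1.83) and 6 (1.78). Chromosome X had the fewest (0.623). Chromosome 17 also had the shortest median length (160 kb), and chromosomes 18 and X had the longest (310 kb).

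The 8 domains with the highest caller scores were 190 to 760 kb long. The first was a 370 kb domain on chromosome X (109685001 to 110055000, score 1.89). It was followed by domains on chromosome 18 (18510001 to 18760000, 1.86), chromosome 10 (103350001 to 103540000, 1.86), chromosome 4 (166035001 to 166400000, 1.85), chromosome 3 (112760001 to 113005000, 1.85) and chromosome 6 (126100001 to 126300000, 1.85). The last 2 lay on chromosome 9 (81785001 to 82545000, 1.84) and chromosome 3 (149680001 to 149930000, 1.84). The chromosome 9 domain held 4 smaller ones. A loop joined the 2 ends, within 50 kb, of the domains on chromosomes X, 10, 4 and 6 and of the first on chromosome 3, with 56 to 132 observed contacts each. The 3 longest domains, 3.51 Mb on chromosome 10 (82360001 to 85865000), 2.80 Mb on chromosome 4 (65480001 to 68275000) and 2.37 Mb on chromosome X (115070001 to 117440000), had low scores of 0.571, 0.931 and 0.599 and no such loop.

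Domains were denser and shorter in bins of positive score. There were 1.73 domains per Mb in positive bins and 0.953 in negative bins, a ratio of 1.82 (interval 1.54 to 2.11, chromosomes resampled; permutation test, adjusted p = 1.75e-05). The density was higher in positive bins on 21 of 23 chromosomes, the exceptions being chromosomes 5 and X. Chromosome 13 entered that count with 1 negative bin. Without the 5 chromosomes with few-bin scores it was higher on 17 of 18, all but X. Those 17 include chromosome 4 (1.26 against 0.776 per Mb), whose sign followed its arms. The widest gaps among chromosomes with block-like scores were on chromosome 6 (2.67 against 0.989 per Mb), chromosome 1 (2.51 against 1.23) and chromosome 10 (2.48 against 1.21). On chromosome X, with 29 positive bins, the order was opposite, 0.448 against 0.664 per Mb. The sign convention is not given, so whether the sign has the same meaning on X is unknown. Median domain length was 210 kb (quartiles 130 and 355 kb) for 2441 domains in positive bins and 287.5 kb (160 and 510 kb) for 1404 in negative bins. The mean log2 length differed by -0.41, positive minus negative, a ratio of 0.752 (interval 0.697 to 0.821; permutation test, adjusted p = 1.75e-05). Among domains scoring above the median the length difference was smaller, -0.16 (unadjusted permutation p = 0.00016). Without the 5 chromosomes with few-bin scores the density ratio was 2.07 (1.83 to 2.31) and the length ratio 0.704 (0.662 to 0.763). With chromosome 4 left out as well they were 2.16 (1.94 to 2.37) and 0.683 (0.653 to 0.717). Median length was shorter in positive bins on 19 of the 22 chromosomes with domains in both signs. It was longer there on chromosome 4, where the sign followed the arms (295 against 242.5 kb), and on chromosome 22 (225 against 160 kb), and equal on chromosome X (310 kb).

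**Figure D2:**
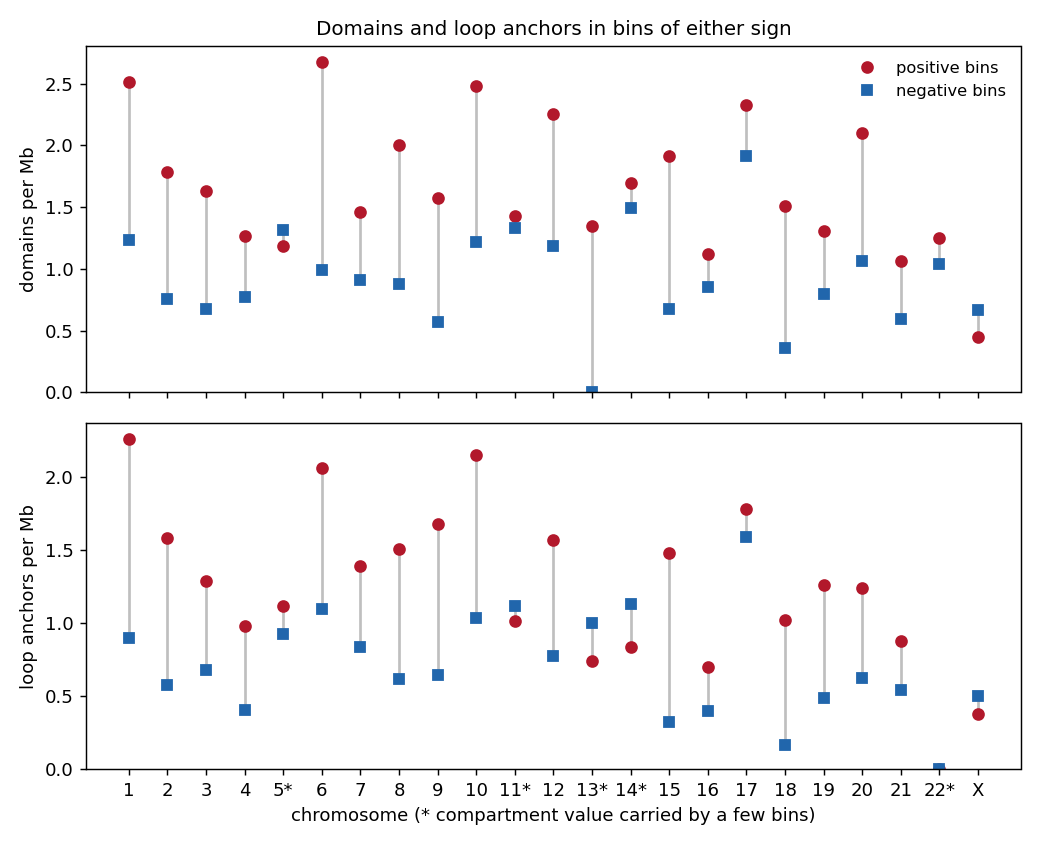
Domains per Mb (upper panel) and loop anchors per Mb (lower panel) in positive bins (red circles) and negative bins (blue squares) of each chromosome (x axis), 1 pooled value each. Asterisks mark the 5 chromosomes whose score is carried by a few bins, and chromosome 13 has 1 negative bin. Domains are denser in positive bins on 21 of 23 chromosomes, and both points of chromosome 22 lie at 0 for anchors.

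**Figure D3:**
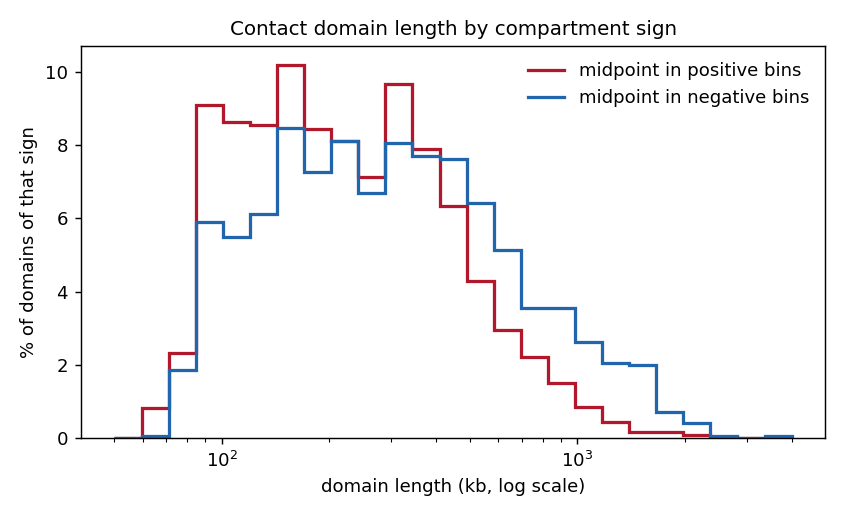
Distribution of contact domain length (x axis, kb, log scale) as the percentage of the domains with midpoint in positive (red) or negative (blue) bins (y axis). The positive distribution lies at shorter lengths, with a median of 210 kb against 287.5 kb.

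Most positions where the compartment sign switched had a domain boundary in a flanking bin, as did most rotated positions. Of 512 switches between neighbouring bins, 469 (91.6%) had a boundary in either flanking bin, against 85.8% by rotation (permutation test, adjusted p = 2.8e-05). A real switch always joins a positive to a negative bin, and these differed in domain density. A rotated switch need not, so the density difference alone can raise the share. The test therefore cannot show that boundaries lie at the switches themselves. The call was lost when only bins with larger absolute scores were kept, where 80 of 93 switches (86.0%) had one against 85.2% by rotation (unadjusted permutation p = 0.872). It was kept under the 5 other alternatives. Without the chromosomes with few-bin scores, 364 of 387 switches (94.1%) had one against 85.8% by rotation (unadjusted permutation p = 1e-05). The density difference between signs was also larger there, so the same limit holds. Domains themselves did not avoid the switches at this resolution. Of 1220 domains that reached into more than 1 bin, 977 (80.1%) kept to 1 sign, against 81.5% by rotation (permutation test, adjusted p = 0.123).

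Loops are point-like peaks of contact between a pair of anchors. The 1507 loops comprised 214 with 5 kb anchors and 1293 with 10 kb anchors, and every pair lay within 1 chromosome. The median anchor distance was 280 kb (interval 260 to 300 kb, chromosomes resampled), with quartiles at 160 and 470 kb. The median enrichment over the donut expectation was 2.71-fold (2.65 to 2.76), with quartiles at 2.40 and 3.20. Among the listed loops, enrichment was higher at longer distances while contacts were fewer. Fewer contacts are expected at longer distances, so a loop there needs a higher enrichment to reach the same significance. The order may therefore reflect the caller's threshold, which was not tested. The median was 2.31-fold on 95 observed contacts for 144 loops up to 100 kb, 2.70-fold on 77 contacts for 509 loops between 200 and 400 kb, and 3.27-fold on 49 contacts for 95 loops between 800 and 2000 kb. Loops with 5 kb anchors had a median enrichment of 3.57-fold on 44 contacts, against 2.63-fold on 80 contacts for those with 10 kb anchors. Chromosome 1 had the most loops (177), followed by chromosomes 6 (131), 2 (112) and 10 (110). Counting loops up to 2 Mb, chromosomes 10 (0.791 per Mb) and 6 (0.775 per Mb) ranked highest, and chromosomes X (0.225) and 16 (0.222) were among the lowest. No loop was listed on chromosome 22, where 40 domains were listed.

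A group of 75 loops (4.98%) spanned more than 2 Mb, and 42 of them more than 10 Mb. They lay on 15 chromosomes, with 14 on chromosome 1, 11 on chromosome 17, 9 on chromosome 9, 8 on chromosome 7 and 7 on chromosome 5. Their median enrichment over the donut was 17.5-fold on 24 observed contacts. Over the highest of the 4 local expectations it was 6.83-fold, against 2.15-fold for the loops up to 2 Mb. Among loops with at least 20 contacts, the 12 with the highest donut enrichment all came from this group. In the order of those 12, the first joined 133030001 to 133040000 and 230040001 to 230050000 of chromosome 2, 97.0 Mb apart, with 33 contacts against 0.0137 expected, a 2408-fold enrichment (95% Poisson interval 1658 to 3382), and 1931-fold over the highest expectation. The second joined 25950001 to 25960000 and 125800001 to 125810000 of chromosome 12 (2262-fold, 1449 to 3366, on 24 contacts, and 37.3-fold over the highest expectation). The third joined 75450001 to 75460000 and 129800001 to 129810000 of chromosome 3 (868-fold, 664 to 1115, on 61 contacts, and 15.7-fold over the highest). The fourth, also the longest of all, joined 8920001 to 8930000 and 236640001 to 236650000 of chromosome 1, 227.72 Mb apart (707-fold, 470 to 1022, on 28 contacts, and 461-fold over the highest). The next 7 all joined 1 anchor on chromosome 9 (130890001 to 130900000) to separate anchors between 92210001 and 92880000, with 29 to 36 contacts. They were enriched 196-fold to 359-fold over the donut but 3.60-fold to 6.39-fold over the highest expectation, that of the vertical neighbourhood. The last joined 21530001 to 21540000 and 29420001 to 29430000 of chromosome 5 (92.9-fold, 70.5 to 120, on 58 contacts, and 23.9-fold over the highest). The other 2 of the 3 longest loops shared an anchor at 234910001 to 234920000 of chromosome 1, paired with 16830001 to 16840000 (78.4-fold over the donut and 2.91-fold over the highest expectation, on 61 contacts) and 16960001 to 16970000 (28.4-fold and 2.22-fold, on 123 contacts).

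Loops lay at the corners of contact domains, where the 2 ends of a domain meet, far more often than by rotation, and their share depended on the tolerance. In all, 952 of 1507 loops (63.2%, Wilson interval 60.7 to 65.6%) had both anchors at the ends of 1 domain, against 52.3 by rotation (permutation test, adjusted p = 1.75e-05). With tolerances of 25 and 10 kb the number at a corner was 830 (55.1%) and 503 (33.4%), against 10.9 and 2.25 by rotation. Against shifts of 50 kb to 1 Mb, which keep the loops in similar surroundings, the number was 92.1 (unadjusted permutation p = 1e-05). The smallest of these shifts lie within the tolerance, so a shifted loop can still meet its own domain. The 92.1 can thus include true overlaps. The share was 66.5% for loops up to 2 Mb and 26.5% (16.2 to 40.3%) for the 49 loops of 1 to 2 Mb. No loop above 2 Mb was at a corner, but only 8 of those 75 lay on a chromosome with a domain long enough to meet the tolerance, so their share was not measurable. Seen from the domains, 948 of 3845 (24.7%) had a loop at their corner. These had a median caller score of 1.38 against 1.15 for the other 2897. The mean scores differed by 0.219 (two-sided permutation within chromosomes, p = 1e-04, the smallest that 10000 draws can give). Median length was 235 kb in both sets. Domains and loops were called on the same contacts, so the overlap is between 2 readings of 1 data set. That limit also holds for the score difference. What the caller's score measures is not given, and contacts at a domain's corner may enter it.

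**Figure D4:**
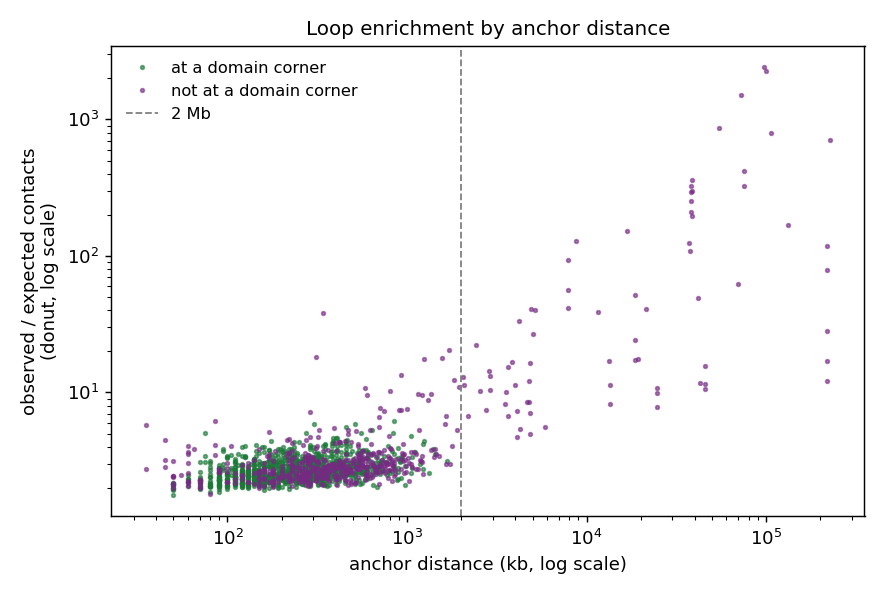
Enrichment of each loop (y axis, observed over donut-expected contacts, log scale) against anchor distance (x axis, kb, log scale), 1 point per loop. Green points lie at a domain corner, purple points do not, and the dashed line marks 2 Mb. Loops up to 2 Mb have quartiles of 2.38 and 3.12 and reach 38.0-fold, and the 75 longer ones have quartiles of 10.7 and 122 and range from 4.73-fold to 2408-fold, and for only 8 of these was a domain long enough for a corner match listed on the chromosome.

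Loop anchors, like domains, were denser in positive bins. There were 1.37 anchors per Mb in positive and 0.733 in negative bins, a ratio of 1.87 (interval 1.59 to 2.19, chromosomes resampled; permutation test, adjusted p = 1.75e-05). Anchor density was higher in positive bins on 18 of 23 chromosomes and lower on chromosomes 11, 13, 14 and X, while chromosome 22 had none. The entry of chromosome 13 rests on 1 anchor in its only negative bin. Without the 5 chromosomes with few-bin scores the ratio was 2.16 (1.91 to 2.43), and 17 of 18 chromosomes were higher in positive bins, all but X. Those 17 include chromosome 4, whose sign followed its arms. With it left out as well the ratio was 2.23 (1.96 to 2.48). On chromosome 18 the densities were 1.02 and 0.167 per Mb, and on chromosome 15 they were 1.48 and 0.324. Of all loops, 63.2% had both anchors at the ends of 1 domain, so the anchor result partly repeats that of domain density. Anchors away from domain corners were not compared apart. Of 123 loops over 1 Mb with a score other than 0 at both anchors, 98 (79.7%) had anchors of the same sign, against 67.4% by rotation, which did not pass the threshold (permutation test, adjusted p = 0.0632). Without the 5 chromosomes with few-bin scores it was 80.6% against 64.3% (unadjusted permutation p = 0.0342). Of the 123 loops, 74 were longer than 2 Mb, many of them close to one another.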

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

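The settings that left out the few-bin chromosomes, chromosome 4 or loops over 2 Mb, or shifted loops by at most 1 Mb, were chosen after the data were seen. The share of positive bins on the autosomes was also added then, whereas autosomes only was a planned setting for the tests. All p-values here are unadjusted permutation p-values. The differences between signs in domain density, domain length and anchor density, and the overlap of loops with domain corners, kept their direction and passed the threshold under every alternative run (7, 7, 8 and 9 of them), with p-values of at most 0.00081, but their sizes moved: 503 of 1507 loops (33.4%) were at corners with a 10 kb tolerance, 830 (55.1%) with 25 kb and 720 (47.8%) with domains scoring above the median, among which the log2 length difference was -0.16. Over all 7 tests, 44 of 50 alternatives left the call as it was and none reversed a call. Keeping only bins in the outer 2 of 3 parts by absolute score lowered the share of switches with a boundary to 86.0%, no longer past the threshold, with 93 switches in place of 512. The share of domains within 1 sign passed the threshold, below the rotated share, without the few-bin chromosomes and chromosome 4 (79.1%, permutation p = 0.0457) and for domains scoring above the median (78.6%, p = 0.0435). The share of loops over 1 Mb with anchors of 1 sign passed without the few-bin chromosomes (80.6%, permutation p = 0.0342), without these and chromosome 4 (79.8%, p = 0.0458) and with 10 kb anchors only (80.5%, p = 0.0414). With 5 kb anchors only it was 7 of 10, or 70%, against 73.5% by rotation. Keeping fewer bins leaves fewer switches by construction. For the other changed calls the cause was not tested. Positive bins made up 46.7% without the few-bin chromosomes. Domains scoring above the median numbered 1922 by construction, and loops with 5 kb anchors numbered 214, with a median distance of 242.5 kb. Median loop enrichment was 2.78 under the stricter FDR, 3.57 with 5 kb and 2.63 with 10 kb anchors only. No paired analysis was possible because the tables hold 1 group with no column per replicate, and for the same reason no replicate could be left out. The gene, gene-list and motif alternatives and the gene-density orientation of the sign were not run, for want of an annotation and sequence of the same build. Depth sets the counting error of loop enrichment: with 5 kb anchors the median pixel held 44 contacts, and loops over 2 Mb held a median of 24.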

Other observations

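Every test in this part was chosen after the results were seen, except that of loop anchors beside stretches without a score, whose count by bin was also added afterwards.

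Anchors rarely took part in several loops. Among loops up to 2 Mb, touching anchors merged into 2567 sites, of which 274 (10.7%) served 2 or more loops, 23 served 3 and none served more. Sites with 3 loops included 23420001 to 23430000 of chromosome 1, with partners at 90 to 180 kb, 46570001 to 46590000 of chromosome 19, with partners at 50 to 180 kb, and 22280001 to 22300000 of chromosome 10, with partners at 310 to 1070 kb. These were chosen after their values were seen. By contrast, among loops over 2 Mb single sites served 9 loops on chromosome 9 (130890001 to 130900000), 5 on chromosome 1 (234910001 to 234920000) and 4 on chromosome 17 (62910001 to 62920000).

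Loops, like domains, were shorter in positive bins. Loops up to 2 Mb with midpoint in a positive bin had a median anchor distance of 255 kb (926 loops), against 290 kb in negative bins (505 loops), a ratio of 0.829 between geometric means (permutation test, adjusted p = 1.5e-05). Their enrichment was close to equal, 2.63-fold against 2.77-fold at the median (ratio of geometric means 0.971, permutation test, adjusted p = 0.0292), and did not pass without the few-bin chromosomes (2.64 against 2.78, adjusted p = 0.0989). These 2 comparisons were adjusted together with that of domain length. Of the loops up to 2 Mb, 66.5% had both anchors at the ends of 1 domain, so the distance result partly repeats that of domain length. Enrichment was not compared between signs at equal distance.

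No biological explanation was tested for the 3 patterns that follow, because the design holds 1 group.

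The first pattern is the few-bin scores of chromosomes 5, 11, 13, 14 and 22: if their sign marked the same kind of region as elsewhere, domains should be denser in positive bins by about the 0.952 per Mb of the other 18 chromosomes (interval 0.743 to 1.15). The difference was 0.0382 per Mb (interval -0.0681 to 0.208), which argues against reading the sign there as on the other chromosomes. A position beside an unscored stretch or chromosome end, within 2 bins, was found for the top bin on 2 of the 5, chromosomes 5 and 13. Those of chromosomes 11, 14 and 22 lay 25, 38 and 5 bins away. The distances argue against such a position for chromosomes 11 and 14. For chromosome 22 the answer depends on the cut of 2 bins, so it stays open. The top bins of chromosomes 5 and 13 also held an anchor of a loop with enrichment above the 95th percentile (8.76-fold), against 3.26% of bins in general (one-sided exact binomial p = 0.00995), so a disturbed local contact map may have set the score there. The top bins of chromosomes 11 and 14 held no loop anchor. No loop was listed on chromosome 22, so its top bin could not hold one, although it counts among the 5 of the binomial test. That explanation stays open for chromosomes 11, 14 and 22. On chromosomes 5 and 13 it cannot be told apart from the position beside an unscored stretch or chromosome end.

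The second pattern is the 75 loops over 2 Mb, which did not lie independently of one another, since 46 had another such loop with both anchors within 1 Mb, against 3.45 (95% range 0 to 8) in 2000 random placements (permutation p = 0.0005, the smallest these can give). In 25 of them (33.3%) the horizontal and vertical expectations differed at least 3-fold, with at least 2 contacts expected on the larger side. These 25 shared 8 raised anchor sites and may be pieces of a line of contacts that runs from 1 raised bin rather than separate peaks, but only 9 shorter loops had as low a donut expectation, too few for a comparison, so this stays open. Of their anchors 3.33% (5 of 150) lay in or beside an unscored bin, against 0.349% of those of shorter loops (10 of 2864), or with each 1 Mb bin counted once 3 of 81 bins (3.70%) against 6 of 1146 (two-sided Fisher exact p = 0.0174), which can concern few of the loops. Some of the loops over 2 Mb had nearly equal lengths. All 3 on chromosome 4 spanned 45.88 to 45.89 Mb, and some of the 11 on chromosome 17 spanned 4.8 to 4.82 Mb. These were picked after their values were seen, and their cause was not tested. Rearranged segments of this cell line, duplicated sequence and true long contacts all stay open, as untested. No list of rearrangements of this line and no sequence of this build was at hand.

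The third pattern is the uneven number of loops per chromosome. Over the 22 chromosomes with loops, loops up to 2 Mb per Mb had a Pearson correlation of 0.358 (permutation p = 0.103, adjusted 0.119) and a Spearman correlation of 0.361 (p = 0.101, adjusted 0.101) with the distance-adjusted expected contacts of their loops, a stand-in for depth that is itself read from called loops. Without chromosomes 10 and 19, the farthest from the median, Pearson's r was 0.186. Domains per Mb gave 0.342 (permutation p = 0.119) and 0.380 (permutation p = 0.0822, adjusted 0.101), so with 22 chromosomes depth cannot be told apart from other sources of the unevenness. The missing loops of chromosome 22 are not explained by few domains: at the 0.396 loops per domain of the other chromosomes, its 40 domains would go with 15.8 loops, and at the lowest of any other chromosome (0.269) with 10.8, against 0 listed. Whether chromosome 22 was left out of loop calling or merging stays open, as untested.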
